A study of Homo sapiens with 12 samples.

How the data were processed

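The study profiled MDA-MB-231 cells, an established human triple-negative breast cancer line, after 4 h with 10 nM AZD0095 or with its solvent DMSO. AZD0095 is an inhibitor of the lactate exporter MCT4, the product of SLC16A3. RNA-seq measured transcript levels and ribosome profiling measured the mRNA fragments protected by ribosomes, each in 3 DMSO and 3 AZD0095 libraries, 12 libraries in all. Groups and replicate numbers were taken from the labels. The labels do not say that replicates were separate cultures, so p-values measure the spread between these libraries, which may be technical.

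Per the labels' protocols, RNA was purified directly from cells for RNA-seq. For ribosome profiling the lysate of cycloheximide-treated cells was freed of nuclei and mitochondria and digested with RNase I. Ribosomes were then pelleted, rRNA was removed with antisense DNA probes and RNase H, and a small RNA library was made from the fragments. The removal of mitochondria bears on footprints of mitochondrially encoded mRNAs, which depend on how much of the organelle stays in each lysate. The RNA libraries carry the words total RNA in their titles and polyadenylated RNA as their molecule, and which of these applies is not settled here.

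The authors deposited FPKM values, fragment counts scaled to gene length and to mapped reads, in a table for each library with Ensembl gene IDs and symbols. Per the submitters' processing notes, fastp, Bowtie2, STAR and the genome build hg38 were used; their roles and versions, the read counter, the annotation and the FPKM formula are not given in the sources used here. Each table held the same 6785 genes, and the lowest of all values was 1.002, so the listed genes are those above 1 FPKM in every library. Such a list leaves out genes that were near or below that level in any library, including genes switched fully on or off and genes with few footprints. After 8 repeated entries with the same symbol and the same 12 values were removed, 6777 genes were tested. Of the IDs, 11 came without a symbol and were kept under their ID. A gene name table matched 6776 of the IDs, 6766 with the same symbol. Gene positions came from a RefSeq table of GRCh38.p14, the same genome build as hg38, matched by symbol. Reads shared between paralogs or pseudogenes, as for ribosomal protein genes and histone genes, could be split in ways not given in the sources used here, so single members of such families are uncertain.

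Depth was recovered for the footprint libraries. Where whole reads were counted, the FPKM values of a gene are whole multiples of what 1 read is worth. The 6 footprint libraries shared such steps, and the total that makes the steps whole gave 107087 to 501351 implied reads per library. Values came to whole reads, within 0.1 of a read in each library, for 1119 genes. Of these, 1081 genes or 15.9% of those listed had an implied length 1 short of a multiple of 3 and were used. The shortest length that gave whole reads was taken, so a gene whose reads share a factor can be given too short a length and too few reads. The rule that chose these genes was revised after a first result of the test on them had been seen. On a simulated table of 6785 genes, built from the lengths and reads of the genes used, the same steps found the depth of 6 of 6 libraries exactly. Of the whole-read genes that the steps recovered, 99.9% had the right counts. Whole-read genes that were missed are not in that share, and lengths unlike those of the genes used were not tried. In the RNA libraries no shared step was found: at most 15 genes shared a ratio between any pair of libraries, against up to 264 for footprint pairs. The depth of the RNA libraries is therefore unknown.

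FPKM values were transformed as log2(FPKM + 1), with a pseudocount of 1, so fold changes are on this scale, which understates the change of genes with low values. Genes with a mean FPKM of at least 1 were kept, a filter that removed 0 genes. RNA and footprints were each compared between AZD0095 and DMSO with a two-sided limma model with moderated variances that follow a trend with expression. Translational efficiency, the ratio of footprint to RNA values, was tested as the interaction of assay and treatment in 1 limma model over all 12 libraries. That model takes 1 spread per gene over both assays, although footprints varied more than RNA. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, and a gene was called at an adjusted p under 0.05. The change of RNA and of footprints was compared across genes by Pearson's r and Spearman's rho without a p-value, since genes are not independent replicates. Shares of summed FPKM were compared by two-sided exact permutation tests. The mean log2 footprint value of 2 lists was also fitted by least squares on treatment and log2 implied depth, chosen after seeing the data.

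Gene lists were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists of each comparison, and again with a correlation estimated from the data. Before the data were examined, the groups, the tests, 34 gene lists, the rule for named genes and most alternatives were fixed. The lists covered lactate handling and acid-base regulation, energy metabolism, lipid synthesis, stress and hypoxia programmes, signalling and inflammatory targets, the cell cycle, histones and their modifiers, translation, the mitochondrion, the lysosome, selenoproteins, noncoding RNAs and markers of luminal, basal, immune and stromal or endothelial cells. Lists with at least 5 tested members were tested, 31 of the 34. A further 6 lists were written after some of their members' values had been seen and are given apart.

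Genes were named by a fixed rule: in each comparison, the 10 called genes with the largest rise and the 10 with the largest fall among those with a mean FPKM of at least 5 and no overlap between groups. Where no gene was called, the 5 genes with the smallest p in each direction were given as not passing. Genes of lactate handling, lactate-linked stress programmes, lipid synthesis and translation were always given. From each called list the 4 members with the smallest p were named, and from other lists up to 2. Of the genes always to be given, SLC16A1, ARRDC4 and DDIT3 were not analysed here, and 1 more is not reported here. A few further genes were named after their values were seen, which is said where they appear.

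The models were tested on simulated values for the 6777 genes, with 50 genes moved by each of 4 sizes. In the RNA comparison, log2 changes of 0.5 were recovered for 68% of the moved genes, of 1 for 100%, of 2 for 98% and of 3 for 100%, with 9 false calls among 192. For footprints the shares were 0%, 6%, 40% and 78%, with 8 false calls among 70. For translational efficiency they were 0%, 18%, 58% and 88%, with 16 false calls among 98. A simulated list of 26 genes moved by 0.4 gave a camera p of 6.3e-26 in RNA and 0.0082 in footprints. Noise was drawn independently for each gene, so this does not test camera on lists whose members correlate.

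Alternatives changed 1 choice at a time: a pseudocount of 0.1, filters of 5 and 50 FPKM, median centring, quantile normalization, a robust variance model, library weights, a replicate block, leaving out each library, an adjusted p under 0.1, a spread estimated per assay, and an estimated correlation for lists. By exception, the spread estimated per assay came with p-values from a normal distribution in place of the moderated test. The filter of 50 FPKM, the removal of mitochondrially encoded genes, the fits without replicate 1 or with replicate 1 as a batch, and a limma-voom fit on the recovered reads were chosen after seeing the data. R 4.3.3 with limma 3.58.1 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.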

Results

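Transcript levels and ribosome footprints were measured in MDA-MB-231 cells, a human triple-negative breast cancer line, treated for 4 h with DMSO or with 10 nM AZD0095, a blocker of the lactate exporter MCT4. Each assay had 3 libraries per treatment, 12 libraries in all, and 6777 genes were tested, all above 1 FPKM in every library. The series asks how lactate that builds up inside cells affects transcription and translation. RNA libraries of a group correlated at 0.989 to 0.997 across genes and footprint libraries at 0.854 to 0.920. The median standard deviation of a gene within a group, on the log2 scale, was 0.09 in DMSO and 0.10 in AZD0095 for RNA, against 0.53 and 0.44 for footprints.

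Footprint libraries were shallow and unequal in depth. The DMSO libraries held an implied 123859, 107087 and 192324 reads and the AZD0095 libraries 141122, 217366 and 501351, so the mean depth with AZD0095 was 2.03 times that with DMSO. Among the 1081 genes whose values came to whole reads, within 0.1 of a read, the median gene had 5 to 10 reads in the DMSO libraries and 7 to 27 in the AZD0095 libraries. The share of those genes with 3 or fewer reads was 30.6%, 35.5% and 17.5% in the DMSO libraries and 24.7%, 11.7% and 2.4% in the AZD0095 libraries. The depth of the RNA libraries is unknown. On the first principal component of footprints DMSO replicate 2 stood apart, at 56.1 with the others between -18.9 and 2.95, and on the second DMSO replicate 1, at 52.8 with the others between -27.7 and 0.383.

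The RNA comparison addressed which transcripts changed after 4 h with AZD0095. DDIT4, which encodes an inhibitor of mTORC1 signalling, rose most, from 12.1 ± 1.86 to 60.1 ± 2.36 FPKM (SD, n = 3), a log2 fold change of 2.23 ± 0.10 (SE, limma adjusted p = 6.0e-05). CTH, the enzyme that makes cysteine from cystathionine, rose from 12.2 ± 0.812 to 32.3 ± 1.44 FPKM (log2 fold change 1.33). TRIB3, a pseudokinase known as a target of the transcription factor ATF4, went from 13.3 ± 0.790 to 34.5 ± 2.10 FPKM (1.31). ERRFI1, a feedback inhibitor of the epidermal growth factor receptor, rose from 226 ± 11.7 to 497 ± 19.3 FPKM (1.13). The others of the 10 largest rises were the cyclin CCNG2 (1.30), the lipoprotein receptor VLDLR (1.25), the N-acetylglutamate synthase NAGS (1.19), the kinase PIM1 (1.05), the diacylglycerol kinase DGKA (0.99) and GSE1 (0.95). All 10 kept their call under each of 17 alternatives, with an adjusted p of at most 0.047. Among these alternatives the fit without a filter equals the main fit, and an adjusted p under 0.1 cannot lose a call. In hg38 the DDIT4 gene, ENSG00000168209, spans chromosome 10 from 72273924 to 72276036. CTH, ENSG00000116761, lies on chromosome 1 from 70411268 to 70439851, TRIB3, ENSG00000101255, on chromosome 20 from 380760 to 397559, and ERRFI1, ENSG00000116285, on chromosome 1 from 8011727 to 8026309.

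The largest falls included a pair of cytochrome P450 enzymes known as targets of the aryl hydrocarbon receptor. CYP1A1 went from 19.9 ± 4.46 to 8.13 ± 1.64 FPKM (SD, n = 3), a log2 fold change of -1.19 ± 0.18 (SE, limma adjusted p = 0.0083), and CYP1B1 from 38.7 ± 1.71 to 17.7 ± 1.45 FPKM (-1.09). ADM, which encodes the vasodilator peptide adrenomedullin, fell from 48.2 ± 0.942 to 23.1 ± 1.14 FPKM (-1.03). The metalloprotease ADAMTS1 (-0.90), the nuclear receptor coactivator NCOA5 (-0.99), SHISA2 (-0.93) and the phosphatase regulator PPP1R10 (-0.80) fell too. So did members of chromatin complexes, namely the acetyltransferase subunit ING3 (-0.88), the remodeller subunit BPTF (-0.85) and ZZZ3 (-0.83). The calls of these last 3 and of CYP1A1 were lost without some libraries, while their log2 fold changes stayed between -1.35 and -0.66: without DMSO replicate 2 the adjusted p was 0.051 for ING3, 0.054 for CYP1A1, 0.074 for BPTF and 0.13 for ZZZ3. BPTF was also lost without AZD0095 replicate 2 (0.064) or 3 (0.053), and ZZZ3 without DMSO replicate 1 (0.12) or 3 (0.076) or AZD0095 replicate 2 (0.15) or 3 (0.1). In hg38 CYP1A1, ENSG00000140465, spans chromosome 15 from 74719542 to 74725528, CYP1B1, ENSG00000138061, chromosome 2 from 38067509 to 38076151, and ADM, ENSG00000148926, chromosome 11 from 10305073 to 10307397.

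**Figure D1:**
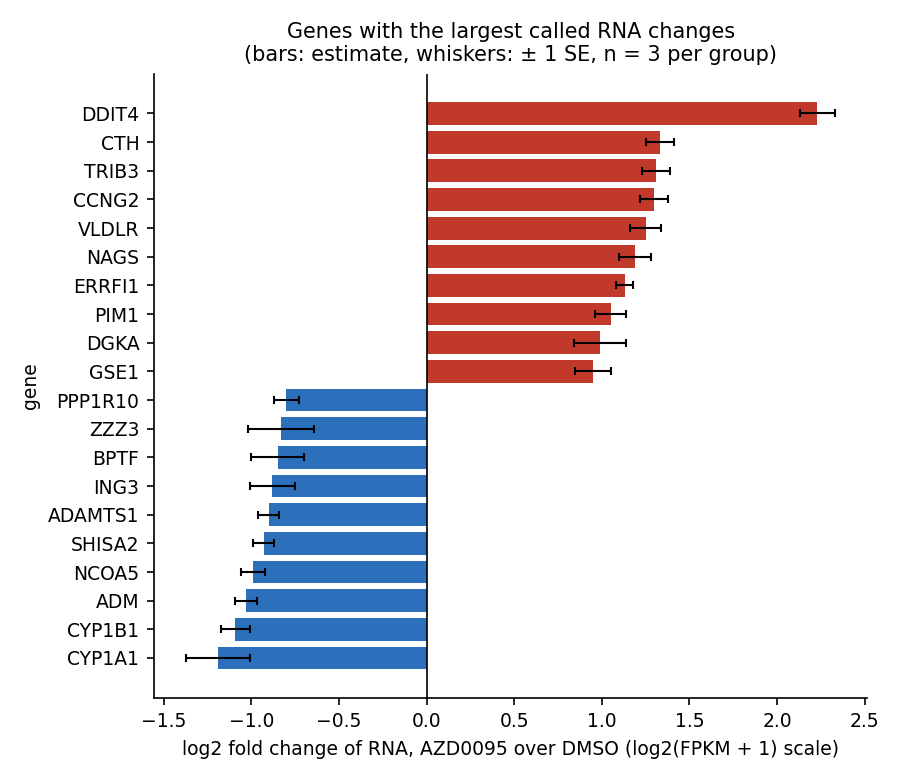
Log2 fold change of RNA on the log2(FPKM + 1) scale, AZD0095 over DMSO, for the 10 called genes with the largest rise and the 10 with the largest fall by the fixed rule, with whiskers of 1 SE (n = 3 per group). The bars run from 2.23 for DDIT4 to -1.19 for CYP1A1.

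In all, 545 of the 6777 genes were called in RNA, 341 higher and 204 lower with AZD0095. Their median absolute log2 fold change was 0.41 and 12 passed a 2-fold change. At an unadjusted p under 0.05 there were 1637 genes, where 339 would be expected by chance. The groups did not overlap for any of the 545, against 1978 or 29.2% of all genes tested and a chance share of 10%. Among the named genes DDIT4, CTH and ERRFI1 stood far outside the replicate spread, while most called genes moved by less than 2-fold. The 2 replicate 1 libraries stood apart from the others of their groups on the second principal component of RNA (28.5% of the variance), at 3.18 for DMSO and 12.2 for AZD0095, with the other libraries between -7.90 and -0.0168. On the first component (52.6%) the DMSO libraries were at 12.4, 6.56 and 4.00 and the AZD0095 libraries at -0.597, -9.98 and -12.4. There AZD0095 replicate 1 lay nearer to DMSO replicate 3 than to the other AZD0095 libraries. Replicates 2 and 3 alone gave 1395 called genes, 656 higher and 739 lower, of which 538 were among the 545. Of these 1395 genes, 90.9% changed in the same direction in the pair of replicate 1 libraries, which was not used to call them. That pair has 1 library per treatment, so it gives no p-value. A model with replicate 1 as a batch gave 1660 called genes, 874 higher and 786 lower. The count also depended on single libraries: it was 280, 100 and 249 without DMSO replicate 1, 2 and 3, and 1112, 116 and 214 without AZD0095 replicate 1, 2 and 3.

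Transcripts of the lactate machinery itself were not called. SLC16A3, the gene of the drug's target, was at 98.4 ± 9.92 FPKM in DMSO and 104 ± 5.85 FPKM in AZD0095 (SD, n = 3), a log2 fold change of 0.09 ± 0.08 (SE, limma adjusted p = 0.56). Its gene, ENSG00000141526, spans chromosome 17 from 82217934 to 82240086 in hg38. BSG, the chaperone of MCT transporters (0.09), and the lactate dehydrogenase genes LDHA (0.08) and LDHB (0.00) were not called either. With 1 library left out SLC16A3 ran from 0.00 to 0.14 and BSG from 0.03 to 0.14. The transcription factor MYC (0.03), the sterol synthesis gene HMGCS1 (-0.11), the ribosomal protein gene RPS6 (-0.04) and the elongation factor EEF2 (0.04) were likewise within the replicate spread. VEGFA, a growth factor gene known to respond to hypoxia and to ATF4, rose from 37.8 ± 2.17 to 69.4 ± 8.37 FPKM (0.85, limma adjusted p = 0.0022). Of the list of lactate transport and metabolism genes, 1 of 7 members rose, 0 fell and 6 did not pass (camera adjusted p = 0.51), and 1 rose when adjusted over the list alone. The member that rose, AARS1 (0.45), is an alanyl-tRNA synthetase that was put in the list for its reported lactate binding, and SLC16A7, a further transporter, was at -0.12. The gene of a luminal keratin, KRT19, rose by 0.31, a call lost without DMSO replicate 2 (adjusted p = 0.064).

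Genes of the integrated stress response, a programme driven by ATF4 that supplies amino acids and limits protein synthesis, rose as a group. Of 26 members tested, 16 rose, 0 fell and 10 did not pass, with a median log2 fold change of 0.34 (camera adjusted p = 2.8e-12), and 17 rose when adjusted over the list alone. With an estimated correlation the adjusted p was 0.063. The members with the smallest p were DDIT4 (2.23), CTH (1.33), TRIB3 (1.31) and the amino acid transporter SLC38A2, at 115 ± 8.64 FPKM in DMSO and 206 ± 6.70 FPKM in AZD0095 (0.84, SD, n = 3). ATF4 itself rose by 0.36 ± 0.05 (SE, limma adjusted p = 0.0063). The serine synthesis enzymes PHGDH (0.37), PSAT1 (0.46) and PSPH (0.78) and the transcription factor CEBPB (0.89) were among the risen members and were named after their values were seen. The call of PSAT1 was lost without DMSO replicate 2 (adjusted p = 0.068) or AZD0095 replicate 2 (0.055), and that of PHGDH without any RNA library but AZD0095 replicate 1, with an adjusted p of at most 0.11.

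Targets of MondoA, a transcription factor that senses glycolytic sugar phosphates, rose as well. Of 6 members, 4 rose, 0 fell and 2 did not pass, with a median log2 fold change of 0.30 (camera adjusted p = 9.0e-04; adjusted p = 0.17 with an estimated correlation), and 4 rose when adjusted over the list alone. They were the arrestin genes ARRDC3 (0.61) and TXNIP (0.24), an inhibitor of glucose uptake, the glycolytic regulator PFKFB3 (0.39) and the transcription factor KLF10 (0.35). The list also held MLXIP, which encodes MondoA, its paralog MLXIPL and their partner MLX. The 2 members that did not pass were of these and not targets. Glycolysis genes were called higher with a small median of 0.07 (camera adjusted p = 0.015; adjusted p = 0.56 with an estimated correlation): 3 of 18 members rose, 0 fell and 15 did not pass, and 4 rose when adjusted over the list alone. The risen members were the glucose transporter SLC2A3 (0.81), PFKFB3 and the hexokinase HK1 (0.28), while the enolase ENO2 was at 0.29 and not called (adjusted p = 0.062; 0.012 with replicate 1 as a batch, 1.3e-04 to 0.23 over all alternatives). Without AZD0095 replicate 3 the glycolysis list was not called (adjusted p = 0.11). Of these genes SLC2A3 kept its call without each library in turn. ARRDC3 lost it without DMSO replicate 2 (adjusted p = 0.071) or 3 (0.051) or AZD0095 replicate 2 (0.072), and PFKFB3 without DMSO replicate 2 (0.088) or AZD0095 replicate 2 (0.075) or 3 (0.053). TXNIP, HK1 and KLF10 lost it without most libraries: TXNIP reached 0.1 and HK1 0.13 without DMSO replicate 2, both also failing without DMSO replicates 1 and 3 and AZD0095 replicates 2 and 3, and KLF10 reached 0.11 without DMSO replicate 2, failing also without DMSO replicate 3 and AZD0095 replicates 2 and 3. HK1 was lost too with median centring (0.06) and quantile normalization (0.072).

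Immediate early genes, which respond within minutes to growth factors and stress, were called higher as a list, with a median log2 fold change of 0.09 (camera adjusted p = 0.014; adjusted p = 0.34 with an estimated correlation). Of 20 members, 6 rose, 1 fell and 13 did not pass, and 7 rose and 2 fell when adjusted over the list alone. DUSP5, a phosphatase that inactivates ERK (0.85), IER3 (0.50), JUNB (0.48) and KLF4 (0.43) rose, and IER5, named after its value was seen, fell by 0.41. Targets of p53 were called higher with a median of 0.25 (camera adjusted p = 0.015; adjusted p = 0.31 with an estimated correlation): 4 of 8 members rose, 0 fell and 4 did not pass, and 4 rose when adjusted over the list alone. The risen members were the death receptor TNFRSF10B (0.48), the stress cytokine GDF15 (0.66), the cyclin-dependent kinase inhibitor CDKN1A (0.30) and GADD45A (0.28). The p53 list was not called without AZD0095 replicate 3 (adjusted p = 0.058) or with a filter of 5 FPKM (0.12). DUSP5, IER3 and JUNB kept their calls without each library in turn; KLF4 lost it without DMSO replicate 2 (0.059) or AZD0095 replicate 2 (0.058), and IER5 without those (0.086 and 0.071) or DMSO replicate 3 (0.055). Each of the 4 p53 targets lost its call without DMSO replicate 2 (0.056 to 0.15) or without AZD0095 replicate 2 (0.075 to 0.11) or 3 (0.053 to 0.098). GDF15 was also lost without DMSO replicate 1 (0.059) or 3 (0.066), CDKN1A without DMSO replicate 1 (0.061) and GADD45A without DMSO replicate 3 (0.096).

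Cell cycle transcripts were lower as groups, by small amounts. Among 20 genes of the G1/S transition, 3 fell, 0 rose and 17 did not pass, with a median log2 fold change of -0.13 and 19 of 20 negative (camera adjusted p = 9.9e-05; adjusted p = 0.17 with an estimated correlation), and 3 fell when adjusted over the list alone. They were the cyclins CCNE2 (-0.67) and CCND1 (-0.19) and the uracil glycosylase UNG (-0.32), while the replication checkpoint gene CLSPN was at -0.45 and not called (adjusted p = 0.09; 7.4e-04 with replicate 1 as a batch, 4.0e-04 to 0.26 over all alternatives). Among 21 genes of G2 and mitosis, 4 fell, 1 rose and 16 did not pass, with a median of -0.16 (camera adjusted p = 2.9e-04; adjusted p = 0.58 with an estimated correlation), and 7 fell and 1 rose when adjusted over the list alone. The mitotic kinases AURKA (-0.42) and PLK1 (-0.21) and BIRC5 (-0.24) fell, as did the kinesin CENPE (-0.46), named after its value was seen, whereas the phosphatase CDC25C rose (0.45). Each of these 8 calls was lost without DMSO replicate 2 (adjusted p of 0.065 for CDC25C, 0.071 for AURKA, 0.088 for UNG, 0.1 for CCNE2, 0.12 for BIRC5, 0.14 for PLK1 and 0.15 for CENPE and CCND1) and without AZD0095 replicate 2 (0.055 to 0.17). AURKA was also lost without AZD0095 replicate 3 (0.062), and CCNE2, CCND1, BIRC5, PLK1 and CENPE without DMSO replicate 1 (0.072 to 0.13) or 3 (0.053 to 0.13) or AZD0095 replicate 3 (0.079 to 0.14). CCND1 was not called with median centring (0.052).

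Targets of YAP and TGF-beta signalling were called lower, with a median log2 fold change of -0.12 (camera adjusted p = 0.015; adjusted p = 0.58 with an estimated correlation). Of 14 members, 4 fell, 1 rose and 9 did not pass, and 6 fell and 1 rose when adjusted over the list alone. The matrix protein gene THBS1 fell from 522 ± 48.3 to 306 ± 29.6 FPKM (SD, n = 3; -0.77, limma adjusted p = 0.0029), and tissue factor F3 (-0.31), CCN2 (-0.35) and TGFB2 (-0.37), the last named after its value was seen, fell too. CCN1, another matrix protein gene, rose by 0.37. The list was not called without DMSO replicate 3 (adjusted p = 0.073) or AZD0095 replicate 1 (0.12). CCN2 lost its call without DMSO replicate 2 (0.088) or 3 (0.059) or AZD0095 replicate 2 (0.064), and TGFB2 without any library but AZD0095 replicate 1, with an adjusted p of 0.059 to 0.075.

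**Figure D2:**
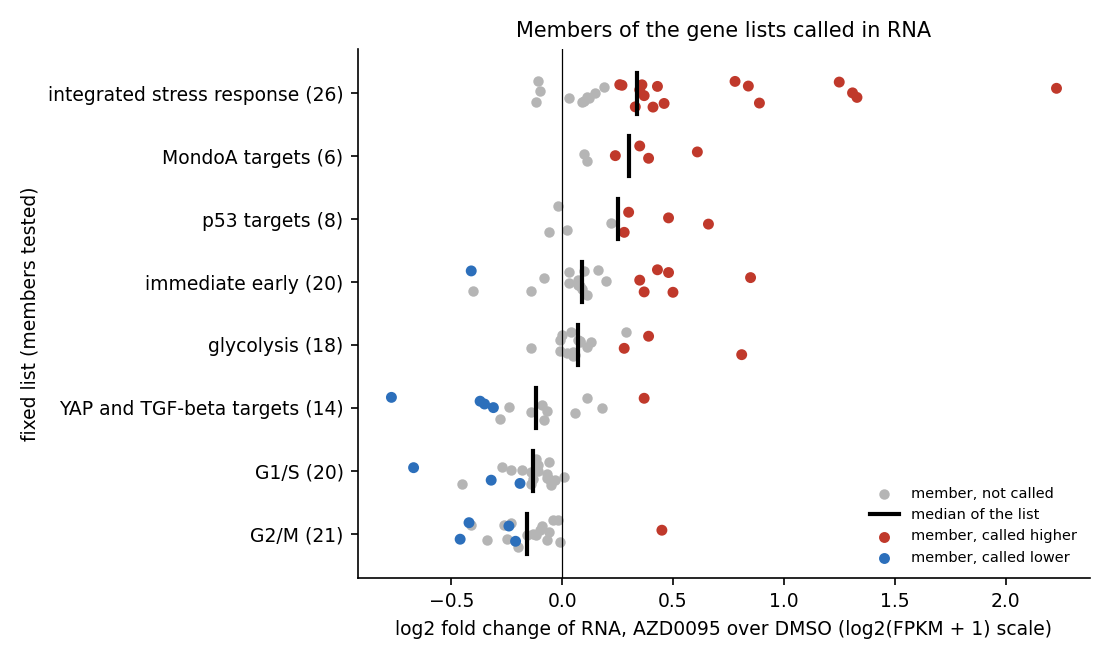
Log2 fold change of RNA on the log2(FPKM + 1) scale, AZD0095 over DMSO, for each member of the 8 called lists, with black bars for the list medians and colours for called members. Medians run from 0.34 for the integrated stress response to -0.16 for G2/M, and 0 of the 8 lists kept its call with an estimated correlation.

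Some inflammatory, hypoxia, protein-folding and antioxidant genes were called, though their lists were not. Of 14 NF-kB and inflammatory genes, 5 rose and 2 fell (camera adjusted p = 0.18): CXCL1 (0.48), IL6 (0.59), CXCL8 (0.65), IL11 (0.41) and NFKB2 (0.27) were higher, and CCL2 (-0.75) and NFKB1 (-0.37) lower, those other than CXCL1 and CCL2 being named after their values were seen, and 7 did not pass. Hypoxia targets split, with DDIT4 (2.23) and VEGFA (0.85) higher, ADM (-1.03) lower and 12 of 15 members not passing (adjusted p = 0.16). Of 18 genes of endoplasmic reticulum stress, the transcription factor XBP1 (0.81) and HERPUD1 (0.42) rose and 16 did not pass (adjusted p = 0.96). The chaperone HSPA8 fell from 2217 ± 129 to 1359 ± 83.0 FPKM (SD, n = 3; -0.71, limma adjusted p = 6.7e-04) and was the only call among 16 heat shock genes, where DNAJA1 was at -0.43 and not called (adjusted p = 0.064; 1.4e-04 with replicate 1 as a batch, 3.6e-05 to 0.22 over all alternatives; list adjusted p = 0.26). NRF2 targets gave HMOX1 (0.56) and, named after its value was seen, the cystine transporter SLC7A11 (0.35) as higher and GCLM (-0.45) as lower among 15, with 12 not passing (adjusted p = 0.91). When adjusted over the list alone, 5 NF-kB genes rose and 3 fell, 3 hypoxia targets rose and 1 fell, 2 endoplasmic reticulum genes rose and 0 fell, 2 heat shock genes rose and 2 fell, and 2 NRF2 targets rose and 1 fell. Without DMSO replicate 2 the adjusted p reached 0.051 for IL6, 0.064 for HERPUD1, 0.07 for CXCL8 and GCLM, 0.071 for IL11, 0.09 for NFKB1, 0.1 for HMOX1, 0.15 for NFKB2 and 0.17 for SLC7A11. Except for IL6 these calls were lost also without AZD0095 replicate 2 (0.051 to 0.16). IL11, GCLM, HMOX1, NFKB2 and SLC7A11 were lost without AZD0095 replicate 3 (0.052 to 0.12), GCLM, HMOX1, NFKB2 and SLC7A11 without DMSO replicate 3 (0.053 to 0.073), and GCLM, NFKB2 and SLC7A11 without DMSO replicate 1 (0.074 to 0.12). SLC7A11 was not called with quantile normalization (0.056).

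Genes of translation, respiration and cell identity showed few calls. In ribosomal protein genes 0 of 74 were called (camera adjusted p = 0.99), in nuclear genes of oxidative phosphorylation 0 of 74 (0.44), in mitochondrially encoded genes 0 of 13 (0.99), in tricarboxylic acid cycle genes 0 of 20 (0.94), in fatty acid synthesis genes 0 of 14 (0.98), in interferon genes 0 of 14 (0.81), in selenoprotein genes 0 of 14 (0.63), in pH regulators 0 of 5 (0.69) and in replication histones 0 of 6 (0.32), and in each of these 0 when adjusted over the list alone. The fatty acid list had a median of -0.02 and a mean of 0.02, and the tricarboxylic acid list a median of 0.02 and a mean of -0.01, so their signs differed. A single member was called in 6 lists: the initiation inhibitor EIF4EBP1 (0.29) among 32 initiation factors (0.74), MRPL34 (0.28) among 72 mitochondrial ribosomal proteins (0.26), the autophagy receptor SQSTM1 (-0.25) among 31 lysosomal genes (0.51), the acetyltransferase KAT5 (-0.37) among 13 histone modifiers (0.16), PABPC4 (-0.25) among 25 other mRNAs with a 5' terminal oligopyrimidine tract (0.69), and KRT19 (0.31) among 5 luminal markers (0.079). MSMO1 (0.39) and FDFT1 (0.30) rose among 22 cholesterol synthesis genes (0.96), and 0 of 6 basal markers were called (0.96). When adjusted over the list alone, 2 initiation factors rose and 1 fell, 2 cholesterol genes rose and 1 fell, 2 luminal markers rose, 1 gene fell in each of the lysosomal, histone modifier and oligopyrimidine lists, and 0 moved in the mitochondrial ribosome and basal lists. Of the immune list only HLA-DRA was tested (0.06, not called), and 0 members of the noncoding and the stromal or endothelial lists were. All of these calls were lost without DMSO replicate 2, with an adjusted p of 0.064 for KRT19, 0.067 for FDFT1, 0.07 for KAT5, 0.088 for PABPC4, 0.09 for SQSTM1, 0.1 for EIF4EBP1, 0.13 for MSMO1 and 0.16 for MRPL34. All but KRT19 were lost without AZD0095 replicate 2 (0.051 to 0.11) too. Without DMSO replicate 3, EIF4EBP1, KAT5, MRPL34, MSMO1 and SQSTM1 were lost (0.051 to 0.099), without AZD0095 replicate 3 EIF4EBP1, MRPL34, MSMO1, PABPC4 and SQSTM1 (0.054 to 0.14), and without DMSO replicate 1 MRPL34 (0.098) and SQSTM1 (0.054). Across all lists 8 of 31 were called in RNA, 5 higher and 3 lower, 0 of them with an estimated correlation (smallest adjusted p 0.063), and other groupings of the same 6 libraries, which keep part of the treatment difference, gave up to 7 called lists.

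Footprints addressed whether ribosome occupancy changed with the drug. DDIT4 had the smallest p of all genes, going from 117 ± 29.3 to 369 ± 23.5 FPKM (SD, n = 3), a log2 fold change of 1.68 ± 0.29 (SE, limma adjusted p = 0.31), which did not pass. Next in the higher direction were the dehydrogenase DHRS7 (2.43), the signal recognition particle subunit SRP54 (2.17), the chemokine CXCL8 (1.04) and the receptor ERBB2 (3.01). In the lower direction the smallest p belonged to the receptor TNFRSF12A, at 1893 ± 314 FPKM in DMSO and 938 ± 86.5 FPKM in AZD0095 (SD, n = 3, a ratio of 0.50 on the transformed scale, limma adjusted p = 0.34), followed by VKORC1 (-2.01), TMEM147 (-0.99), the ribosomal protein gene RPL13A (-0.80) and RSRP1 (-1.72). SLC16A3 was at 343 ± 53.8 and 371 ± 19.4 FPKM (0.12, limma adjusted p = 0.93). Other genes given in every comparison were TXNIP (0.70), VEGFA (0.71), LDHA (0.49), ATF4 (0.29), LDHB (0.15), EEF2 (0.13), MYC (0.05), BSG (-0.05), RPS6 (-0.17) and HMGCS1 (-0.18), with 0 called. With 1 library left out, the values ran from 0.36 to 1.27 for VEGFA, 0.32 to 0.59 for LDHA and 0.04 to 0.47 for ATF4. In hg38 TNFRSF12A, ENSG00000006327, spans chromosome 16 from 3020368 to 3022383.

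The limma test of footprints called 0 of 6777 genes, with 530 at an unadjusted p under 0.05 where 339 would be expected. The median SE of a footprint log2 fold change was 0.51, against 0.08 in RNA, and groups did not overlap for 878 genes, 13% where chance gives 10%. A limma-voom fit on the recovered reads of the 1081 whole-read genes, chosen after seeing the data, called 5 genes, with 110 at an unadjusted p under 0.05, where the log2 FPKM test on the same genes called 0, with 66. Lower were the mitochondrially encoded MT-CO2 (-1.09), MT-CO1 (-0.82) and MT-ND1 (-0.95) and the ribosomal protein gene RPLP2 (-0.66), and higher was GTF2H5 (1.02), all named after their values were seen. The gene length that the steps of GTF2H5 imply is 5390 bases, which is too long for its coding sequence, so its reads are uncertain. The implied length of MT-ND1, 494 bases, is short of its coding sequence, so its reads are uncertain too.

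Footprints of ribosomal protein mRNAs were lower as a group with AZD0095. Of 74 members 67 had a negative value, with a median log2 fold change of -0.22 (camera adjusted p = 2.5e-13; adjusted p = 0.56 with an estimated correlation), 0 called over all genes and 3 lower when adjusted over the list alone. RPL13A (-0.80), RPL18 (-0.64), RPLP2 (-0.59) and RPL37A (-0.58) had the smallest p, none passing over all genes. These mRNAs took 13.1 ± 0.805% of the summed footprint FPKM in DMSO and 11.4 ± 0.367% in AZD0095 (SD, n = 3, exact permutation p = 0.1, the smallest the design allows), and 9.87 ± 0.0859% and 9.81 ± 0.259% of the RNA sum (exact permutation p = 0.8). Footprints of the 13 mitochondrially encoded mRNAs were lower too, with 13 of 13 negative and a median of -0.84 (camera adjusted p = 1.7e-10; adjusted p = 0.79 with an estimated correlation), 0 called over all genes and 6 lower when adjusted over the list alone. MT-CO3 (-1.31), MT-ND3 (-1.27), MT-ND5 (-1.13) and MT-ATP6, at 1589 ± 214 FPKM in DMSO and 895 ± 519 FPKM in AZD0095 (SD, n = 3), had the smallest p. Single AZD0095 libraries set the size of the mitochondrial value, which was -1.39 without replicate 1 and -0.34 without replicate 3. Mitochondrially encoded mRNAs took 5.88%, 5.28% and 3.87% of the footprint sum in the DMSO libraries and 5.28%, 2.76% and 1.29% in the AZD0095 libraries (exact permutation p = 0.3). The implied depth of these libraries was 123859, 107087 and 192324 reads and 141122, 217366 and 501351 reads, so the share was lowest in the deepest library of each group. Reads of MT-CO1 were 2198, 1544 and 2243 in DMSO and 2570, 2003 and 2038 in AZD0095.

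**Figure D3:**
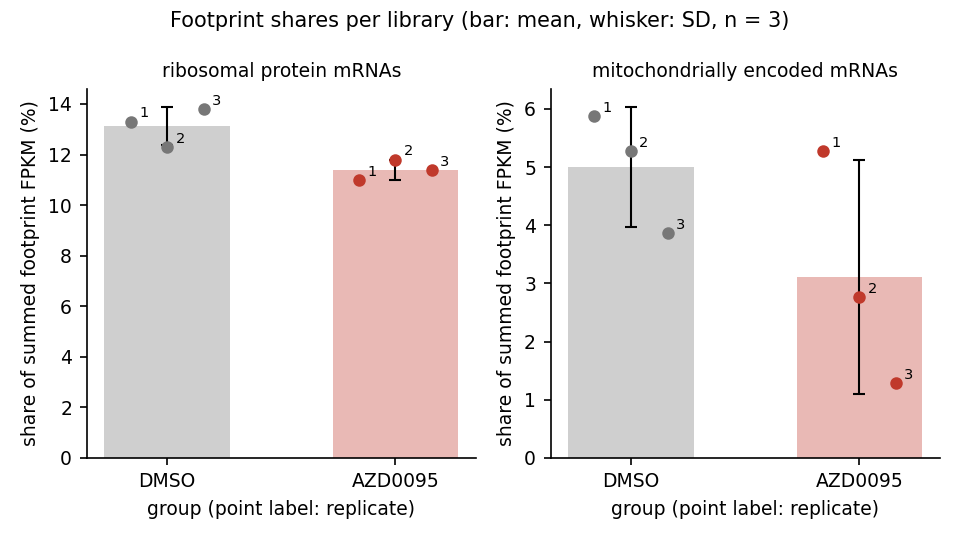
Share of the summed footprint FPKM, in percent, of ribosomal protein mRNAs and of mitochondrially encoded mRNAs in each footprint library, with bars for group means and whiskers for the SD (n = 3). The ribosomal protein share was 13.1% in DMSO and 11.4% in AZD0095 without overlap, and the mitochondrial share of the AZD0095 libraries ran from 1.29% to 5.28%.

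Hypoxia targets and the integrated stress response were called higher in footprints. Among 15 hypoxia targets 12 were positive, with a median log2 fold change of 0.40 (camera adjusted p = 0.014; adjusted p = 0.56 with an estimated correlation), and DDIT4 (1.68), KDM3A (1.86), BNIP3 (0.67) and, in the other direction, ADM (-0.82) had the smallest p. Among 26 genes of the integrated stress response 19 were positive, with a median of 0.25 (camera adjusted p = 0.016; adjusted p = 0.79 with an estimated correlation), and DDIT4 (1.68), CTH (1.63), SLC38A2 (0.79) and XPOT (1.82) had the smallest p. With 1 library left out, ADM ran from -1.35 to -0.53 and XPOT from 1.05 to 2.48. In each list 0 members passed over all genes, and 1 was higher when adjusted over the list alone. The hypoxia call was lost without DMSO replicate 3 (adjusted p = 0.14) and with a filter of 50 FPKM (0.12). The stress response call was lost without DMSO replicate 2 (0.1) or 3 (0.095), without AZD0095 replicate 2 (0.062) or 3 (0.22) and with the same filter (0.12); its median was 0.48 without DMSO replicate 1 and 0.69 without both replicate 1 libraries. These 2 lists and the 2 lower ones were the 4 called of 31, 0 with an estimated correlation. The smallest adjusted p among the other lists was 0.38, for basal markers, and other groupings of the 6 libraries gave up to 3 called lists.

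Genes called in RNA tended to move in the same direction in footprints. Of the 341 genes called higher in RNA, such as DDIT4, CTH and CXCL8, 235 or 68.9% had a positive footprint change, with a median log2 fold change of 0.26. In their central 95%, 10000 random lists matched on footprint FPKM had medians between -0.03 and 0.11. Of the 204 called lower, such as ADM and CYP1B1, 140 or 68.6% had a negative footprint change, with a median of -0.24 against -0.03 to 0.15. The random lists were drawn gene by gene, so these ranges leave out correlation between genes and the spread between libraries. Of all genes 53.1% had a positive footprint change. The median change of translational efficiency was -0.16 for the genes called higher and 0.21 for those called lower, which by construction leans against the RNA change they were chosen on. With median centring the footprint medians were 0.21 and -0.29, and with quantile normalization 0.22 and -0.28. Across all 6777 genes the changes of RNA and footprints correlated at r = 0.15 (rho = 0.12), and across the 545 genes called in RNA at r = 0.47 (rho = 0.45), values over genes, which are not independent replicates. Without AZD0095 replicate 1 of RNA the r over all genes was 0.10.

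**Figure D4:**
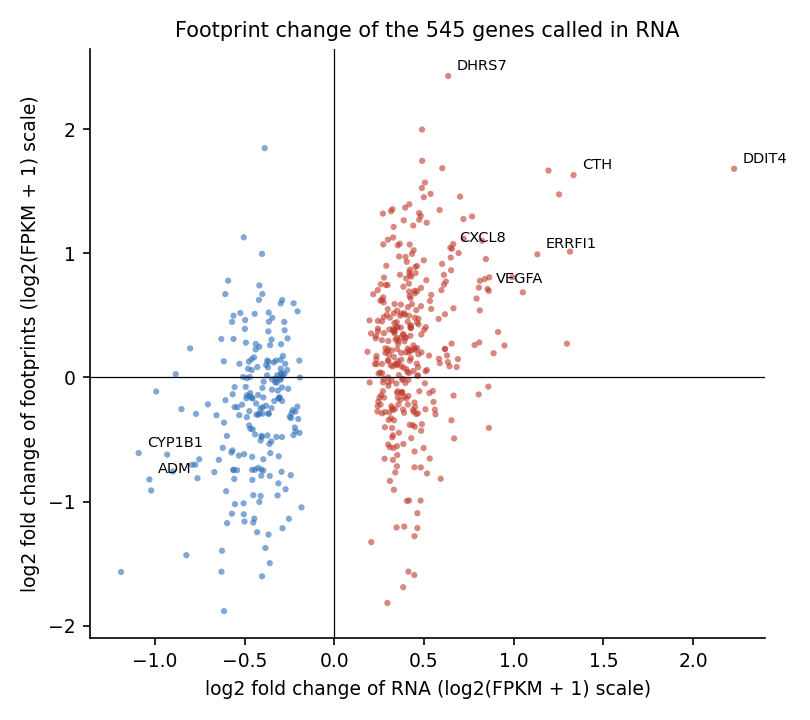
Log2 fold change of footprints against that of RNA, both on the log2(FPKM + 1) scale, for the 545 genes called in RNA (red higher, blue lower), each point a gene. Of the red points 68.9% lie above 0 on the footprint axis and of the blue points 68.6% below it.

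Translational efficiency, the footprint change less the RNA change, addressed whether translation changed beyond transcript levels. The smallest p in the higher direction belonged to the splicing factor SF3B1 (1.44), SRP54 (2.16), GAS2L3 (2.53), the ubiquitin ligase MARCHF7 (1.98) and the kinase RPS6KA3 (2.34), and in the lower direction to TMEM147 (-1.17 ± 0.20, SE, limma adjusted p = 0.2), PRR14 (-2.28), SMIM29 (-2.11), RPL13A (-0.84) and KIAA1191 (-1.53). None of these passed in the limma interaction. SLC16A3 (0.04), ATF4 (-0.07), MYC (0.02), TXNIP (0.46), LDHA (0.42), LDHB (0.15), BSG (-0.15), VEGFA (-0.14), HMGCS1 (-0.07), RPS6 (-0.13) and EEF2 (0.09) did not pass either. The limma interaction called 0 of 6777 genes, with 578 at an unadjusted p under 0.05 where 339 would be expected, and its median SE was 0.47. The model pooled 1 spread per gene over RNA and footprints, whose median standard deviations were 0.09 to 0.10 and 0.44 to 0.53. Its degrees of freedom count RNA libraries that carry little of the noise, so its p-values may be too small. The alternative with a spread estimated per assay also took its p-values from a normal distribution. That ignores the few degrees of freedom and makes small p-values smaller. It called 11 genes, 4 higher and 7 lower, among them SRP54, GAS2L3, TMEM147, PRR14, SMIM29 and RPL13A. The calls can stem from the normal test alone. Leaving out single footprint libraries gave calls as well, named after their values were seen: MBTPS1 (3.54), RPRD1A (2.43), SUMO2 (1.64) and HDGFL2 (-1.85) without DMSO replicate 1, and NFKBIZ (3.06), ARMCX2 (2.53) and RPL13A (-0.96) without DMSO replicate 2.

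Ribosomal protein mRNAs and mitochondrially encoded mRNAs had lower translational efficiency as lists. Of 74 ribosomal protein mRNAs 66 were negative, with a median log2 change of -0.23 (camera adjusted p = 2.0e-13; adjusted p = 0.48 with an estimated correlation), 0 called over all genes and 6 lower when adjusted over the list alone. RPL13A (-0.84), RPS19 (-0.52), RPSA (-0.68) and RPL18 (-0.68) had the smallest p. All 13 mitochondrially encoded mRNAs were negative, with a median of -0.99 (camera adjusted p = 4.8e-06; adjusted p = 0.98 with an estimated correlation), and 0 were lower when adjusted over the list alone. MT-ND5 (-1.28), MT-ND6 (-1.24), MT-ATP6 (-1.02) and MT-ATP8 (-0.99) had the smallest p. The mitochondrial median was -0.46 without footprint library AZD0095 replicate 3. Other mRNAs with a 5' terminal oligopyrimidine tract, which share the regulation of ribosomal protein mRNAs, had a median of -0.01 (adjusted p = 0.94). These were the 2 called of 31 lists, and 60 of 100 splits of the libraries, the real one included, gave as many.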

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

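The test against shallow libraries and the splits were planned before their results were seen; the tests of mRNA levels, of other oligopyrimidine mRNAs, of mitochondrial carry-over and of unequal depth were chosen only after the result was seen.

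Ribosomal protein mRNAs had a footprint change less their RNA change of -0.23 (camera adjusted p = 2.0e-13; adjusted p = 0.48 with an estimated correlation), which drew attention as a difference between the responses of footprints and RNA. Other genes of like footprint FPKM did not fall as far. The footprint median of -0.22 lay at percentile 0 of 10000 random lists matched on footprint FPKM, whose central 95% ran from -0.06 to 0.09. The random lists were matched on FPKM and not on reads. They were also drawn gene by gene, while the members of the list correlated (estimated correlation 0.14). Shallow libraries or the listing of genes by a minimum are therefore not ruled out. Unequal depth stays open. The treatment difference of the list's mean was -0.25 (95% interval -0.45 to -0.04) alone and -0.25 (-0.58 to 0.08) with depth as a covariate. The slope on log2 depth was 0.00 (-0.22 to 0.23), so no trend with depth was seen, but the interval with the covariate holds 0. A lower mRNA level was contradicted, with an RNA median of 0.01 (95% bootstrap interval over members 0.00 to 0.02). That interval leaves out the spread between libraries. By library the mean log2 RNA value of the list was 8.95, 8.99 and 9.00 in DMSO and 9.00, 8.95 and 9.00 in AZD0095. Lower translation of the whole class of mRNAs with a 5' terminal oligopyrimidine tract could not be judged. The other mRNAs of the class had a median of -0.01 (95% bootstrap interval over members -0.25 to 0.12). The rise of DDIT4, an inhibitor of mTORC1, brings up this biological explanation. Chance was not excluded: 60 of 100 splits of the libraries, the real one included, gave as many lists called for translational efficiency, with a highest other count of 6. These counts take any list in either direction, so they do not test this list by itself. Some splits also keep the RNA groups or the footprint groups.

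Mitochondrially encoded mRNAs had a footprint change less their RNA change of -0.99 (camera adjusted p = 4.8e-06; adjusted p = 0.98 with an estimated correlation), which drew attention in the same way. The fall in footprints went with the implied depth of the libraries. The treatment difference of the mean log2 footprint value was -0.94 (95% interval -2.68 to 0.79) alone and -0.07 (-0.91 to 0.76) with depth as a covariate. The slope on log2 depth was -1.01 (-1.57 to -0.44). FPKM is already scaled to that depth, so such a slope restates that mitochondrial reads did not rise with the total. With 6 libraries, and more depth with AZD0095, the fit cannot separate depth from treatment or from carry-over. Carry-over of mitochondria, of which the lysates had been freed, stays open, since the 4.43-fold range among the AZD0095 libraries, against 1.67 between the group means, shows only that these libraries differ. A lower level of mitochondrial RNA was not seen, with an RNA median of 0.07 (95% bootstrap interval over members -0.07 to 0.15). The 13 transcripts moved together (estimated correlation 0.96), so that interval does not measure the spread between libraries. Their share of the RNA sum was 12.5 ± 1.94% in DMSO and 12.9 ± 3.02% in AZD0095 (SD, n = 3, exact permutation p = 0.7). A change of mitochondrial translation with AZD0095 was not tested.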

How the results depend on the processing

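No called list and none of the called genes named in the text changed sign under any alternative, but many calls were lost and some were gained. The 545 RNA calls stayed within 1.5 times that count with a pseudocount of 0.1 (545), a filter of 5 FPKM (517), median centring (532), quantile normalization (529) and a robust variance model (541). They became 3086 with library weights, whose estimation stopped before it converged, and 891 at an adjusted p under 0.1, which by construction adds genes. Both RNA replicate 1 libraries left out gave 1395 and replicate 1 as a batch 1660, both chosen after seeing the data. Leaving out each library in turn gave 100 to 1112 RNA calls. Of the 64 called genes named by the rule, 31 kept their call in every alternative and 33 lost it without a library, and 2 of these also with median centring or quantile normalization. Of the 31 named after their values were seen, 10 kept it and 21 lost it without a library. Among the 133 genes taken for RNA by the rule or later, called or not, those that gained a call numbered 28 with library weights, 21 with replicate 1 as a batch, 21 with the replicate block, 15 without both replicate 1 libraries and 12 without AZD0095 replicate 1. The filter of 1 FPKM removed no gene, so the fit without a filter gave the same values and is no test of the filter. Where a group kept 2 libraries the spread was pooled over the groups. The cause of these changes was not tested.

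With a replicate block on the replicate numbers the RNA calls came to 1622, including all 545, with 0 for footprints and 0 for translational efficiency, and 8, 4 and 2 called lists; of the 6 lists written later, 1 called in RNA, the aminoacyl-tRNA synthetases, was not called with it (adjusted p = 0.096). As a hint from the data, not the design, not every sample correlated best with its own number: deviations of same-numbered RNA libraries correlated at 0.62, 0.09 and 0.49, but DMSO replicate 2 did so best with AZD0095 replicate 3 (0.23). Footprint libraries gave 0.01, -0.02 and 0.09. The numbers were therefore not used as pairs.

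With an estimated correlation camera called 0 of the 31 fixed lists in RNA, 0 in footprints and 0 in translational efficiency. Of the 8 lists called in RNA, the estimate was 0.16 for glycolysis, 0.46 for G2/M and 0.29 for YAP and TGF-beta targets. It was 0.01 for the integrated stress response and G1/S, 0.03 for immediate early genes, -0.03 for MondoA and -0.05 for p53 targets. A higher correlation therefore does not by itself explain the loss for the integrated stress response, whose unadjusted camera p went from 9.1e-14 to 0.002. What else differs between these settings was not tested. Of the 6 lists written later, 2 kept their RNA call with an estimated correlation, growth factor feedback and epithelial junctions (camera adjusted p = 0.029 each). These were adjusted over 6 lists and the fixed ones over 31, so the adjusted values are not alike. Unadjusted, the camera p was 0.0083 for growth factor feedback and 0.0096 for epithelial junctions, against 0.002 for the integrated stress response. Called footprint lists were 2 with a filter of 50 FPKM, which tests fewer genes, and 2 to 4 with a library left out. Called lists for translational efficiency were 1 with the mitochondrially encoded genes removed, which removes that list by construction, and 2 to 3 with a library left out. Footprint calls were 5 by limma-voom on recovered reads and 0 in every other alternative, leaving out libraries included. Calls of translational efficiency were 11 with a spread estimated per assay and a normal test, and 0 to 4 with a library left out. The r between RNA and footprint changes was 0.19 with a filter of 50 FPKM and 0.10 to 0.19 with a library left out. The filter of 50 FPKM, the removal and limma-voom were chosen after seeing the data.

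Among genes that were not called, some signs turned, and the cause was not tested. MYC RNA was -0.02 with library weights, and BSG footprints 0.04 with quantile normalization and 0.04 without both replicate 1 libraries. For translational efficiency MYC was -0.03 with median centring and -0.02 without mitochondrially encoded genes, SLC16A3 -0.01 with median centring and VEGFA 0.14 without all replicate 1 libraries. With a library left out, RNA values ran from -0.08 to 0.05 for LDHB and -0.09 to 0.00 for RPS6. Footprint values ran from -0.43 to 0.07 for HMGCS1, -0.10 to 0.13 for MYC, -0.30 to 0.02 for RPS6, -0.01 to 0.20 for SLC16A3, -0.03 to 0.23 for EEF2 and -0.13 to 0.03 for BSG. Translational efficiency ran from -0.50 to 0.41 for VEGFA, -0.33 to 0.18 for HMGCS1, -0.32 to 0.11 for ATF4, -0.13 to 0.10 for MYC, -0.26 to 0.06 for RPS6, -0.10 to 0.12 for SLC16A3 and -0.07 to 0.19 for EEF2. Footprint depth was low, with medians of 5 to 27 reads among whole-read genes, and simulated log2 changes of 1 with the spread of these libraries were recovered for 6% of genes; whether depth sets this spread was not tested.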

Other observations

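The lists of the next 2 paragraphs were written after some of their members' values had been seen, and their members are named on that basis. Their camera p-values therefore rest in part on values already seen, and describe the lists without testing them independently. They were adjusted over the 6 lists written later, apart from the 31 fixed lists tested. In the last paragraphs the test of a batch was chosen only after the result was seen, while the swap and the splits were planned.

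Transcripts of growth factor feedback and of epithelial junctions rose in RNA. Among 12 genes of the epidermal growth factor receptor, its ligands and its feedback, 8 rose and 0 fell, with a median log2 fold change of 0.37 (camera adjusted p = 4.8e-07; adjusted p = 0.029 with an estimated correlation), and 4 of them are also in lists fixed earlier. ERRFI1 (1.13), the transcription factor ETV5 (0.81) and the ligands AREG (0.79) and HBEGF (0.40) were among the risen, while EGFR itself was at -0.29 and not called (adjusted p = 0.11; 0.0015 with replicate 1 as a batch, 0.0015 to 0.27 over all alternatives). Among 13 genes of epithelial junctions 7 rose and 0 fell, with a median of 0.42 (camera adjusted p = 2.2e-05; adjusted p = 0.029 with an estimated correlation). They included the tight junction genes OCLN, from 6.31 to 10.5 FPKM (0.65), F11R (0.66) and CLDN4 (0.50) and the connexin GJB2 (0.59). Genes for aminoacyl-tRNA synthetases were called higher with a median of only 0.03, 6 of 20 rising, among them AARS1 (0.45), GARS1 (0.43), SARS1 (0.41) and YARS1 (0.33) (camera adjusted p = 0.026; adjusted p = 0.19 with an estimated correlation). This last call was lost without DMSO replicate 3 (adjusted p = 0.06) or AZD0095 replicate 1 (0.18), where its median was 0.00, and with replicate 1 as a batch (0.078). Without DMSO replicate 2 the adjusted p was 0.06 for HBEGF and CLDN4, 0.053 for GJB2 and 0.054 for YARS1, and without AZD0095 replicate 2 it was 0.071 for HBEGF and 0.056 for CLDN4.

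The lists of ribosome biogenesis genes and of SR splicing factors with their kinases were called lower in RNA. Of 64 ribosome biogenesis genes 12 fell and 0 rose, with 58 negative and a median log2 fold change of -0.18 (camera adjusted p = 2.3e-10; adjusted p = 0.074 with an estimated correlation). RRS1, a factor of the large subunit, went from 27.5 to 19.1 FPKM (-0.51), and the kinase RIOK1 (-0.61), the polymerase I subunit POLR1G (-0.43) and the chaperone GRWD1 (-0.42) fell too. Among 15 splicing factors of the SR family and their kinases 3 fell and 1 rose, with a median of -0.20 (camera adjusted p = 6.7e-04; adjusted p = 0.19 with an estimated correlation): SRSF6 went from 84.8 to 49.2 FPKM (-0.78), SRSF1 (-0.40) and SRSF3 (-0.38) fell and the kinase CLK3 rose (0.68). Of 5 targets of the aryl hydrocarbon receptor CYP1A1 and CYP1B1 fell, while NFE2L2 (-0.08), NQO1 (-0.06) and TIPARP (-0.03) were not called. The list median was -0.08 (camera adjusted p = 0.0028, and 0.072 with an estimated correlation). That median ran from -0.05 without DMSO replicate 1 or AZD0095 replicate 2, over -0.14 and -0.15 without DMSO replicate 2 and 3, to -0.30 without AZD0095 replicate 1. None of these 6 lists was called in footprints (smallest adjusted p 0.064) or in translational efficiency (0.79). Without DMSO replicate 2 the adjusted p was 0.059 for RRS1, 0.06 for POLR1G, 0.068 for GRWD1 and 0.065 for RIOK1, SRSF1 and SRSF3. Without AZD0095 replicate 2 these calls were lost as well (0.053 to 0.078), and that of RIOK1 without AZD0095 replicate 3 (0.053).

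Among the replication histones, H2BC5 was at 9.86 ± 0.745 FPKM in RNA and 5436 ± 1307 FPKM in footprints of the DMSO libraries (SD, n = 3), and at 7.86 ± 1.41 and 3872 ± 1029 FPKM in the AZD0095 libraries. H2AC6 was at 23.8 ± 2.01 and 1201 ± 208 FPKM in DMSO and 19.7 ± 0.680 and 1502 ± 268 FPKM in AZD0095. Replication histone mRNAs lack a polyA tail.

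The 2 RNA replicate 1 libraries stood apart from replicates 2 and 3 of their groups. The deviations of both from their group means correlated at 0.62 across genes, which is what a batch difference shared by the pair would give and may raise the spread that the RNA test uses. Swapped labels of the pair were contradicted, since 90.9% of the genes called from replicates 2 and 3 alone changed in the same direction in the pair. No biological explanation was tested.

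Other splits of the libraries were tested in the same way. For RNA 1 of 10 splits, the real one, gave 545 calls, with a highest other count of 0, and 1 of 10 gave 8 called lists, with a highest other count of 7. For footprints 10 of 10 splits gave 0 calls, as the real one did, and 1 of 10 gave 4 called lists, with a highest other count of 3. With 10 splits a share under 0.05 cannot be reached. For translational efficiency 100 of 100 splits reached the real count of 0 calls, the highest other being 11, in a split that kept the RNA groups and exchanged the footprint groups, so that it adds the RNA and footprint changes. Called lists for translational efficiency numbered at least 2 in 60 of 100 splits. Other splits of the RNA libraries called 3 to 7 lists in most cases, but each sets 2 libraries of a treatment with 1 of the other, so part of the treatment difference stays in them.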
